A study of Homo sapiens with 6 samples.

How the data were processed

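RNA from 143B osteosarcoma cells was sequenced in 6 libraries, 3 from cells given PBS and 3 from cells given TPBC-PEG for 24 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. The extraction text speaks of animal tissue although the samples are a cell line, so it may be a general text. The library kit, read length and strandedness are not given in the sources used here.

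The authors deposited 1 table of raw read counts per gene, with 60683 rows named by Ensembl gene identifiers and a column for each of the 6 libraries. Reads were aligned with HISAT2 to GRCh38, per the submitters' processing notes. The HISAT2 version, the counting program, the annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Where counting ignored strand, reads of overlapping genes on opposite strands cannot be told apart, and reads shared by a gene and its pseudogene may be split or dropped. All columns of the table matched a sample, and 0 rows named no gene. Of the rows, 42013 had a symbol in the gene name table, and rows without one held 0.439% of the counts. Coordinates, gene types, exon lengths and exon overlaps came from GENCODE release 29 on GRCh38, which covered 58496 rows. In 30572 rows every library had a count of 0.

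The deposited counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 15846, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) compared TPBC-PEG with PBS with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken from its F statistic. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Library totals ran from 15726323 to 20486584 counts and the common biological coefficient of variation was 4.19%. Sequencing reads without molecular identifiers are not independent molecules, so counting error alone understates the error.

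Before the data were examined, 41 gene lists, the tests, the rule for genes named in the text and the other settings to be tried were fixed. Of 920 list entries 917 matched a row and 827 were measured. Lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. Genes were named by a rule with 4 parts. These were the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM in a group and no overlap between groups; 12 Hippo genes fixed by name; in each list up to 2 called members per direction with the largest change at 1 CPM or more, or the 2 most abundant members where none was called; and the 5 smallest p-values per direction. Some of the genes it gave are not reported here. The rule gave 149 genes, and for 26 of them over 10% of the exon length overlaps another annotated gene.

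The script was tested on simulated data with 200 of 15846 genes changed in a TPBC-PEG against PBS comparison. It recovered 62% of genes changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 14 of 180 calls (7.78%) were false. The changed list was called and 0 of 40 unchanged lists were. Simulated genes were drawn independently, so this does not show how the list tests behave with correlated genes. The changed genes were picked above a minimum PBS level, so recovery at the lowest counts was not tested. When a trend with GC content was put on the simulated TPBC-PEG libraries, the test without an offset made 4291 false calls and the test with the GC offset 14. The main test has no such offset, and with it 88.8% of the genes called in the real data were called again.

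The settings chosen beforehand were DESeq2 size factors, library size alone and upper quartile scaling; no filter and a filter of 1 CPM in 3 libraries; DESeq2 1.42.0 and limma-voom; non-robust estimation; a test against a 1.5-fold change; the replicate number as a block; leaving out each library in turn; and, for lists, an estimated correlation and fry. Chosen after seeing the data were offsets that remove a smooth trend (lowess, span 0.3) with GC content, exon length or expression level, and a run on protein-coding genes alone. GC content was known for 99.2% of tested genes. Random lists matched on mean expression were drawn 10000 times. Figures were drawn with matplotlib. Protein levels, cell survival and light exposure were not analysed here.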

Results

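The study measured messenger RNA by sequencing in 143B cells, a human osteosarcoma cell line derived from the HOS line. The series title names HIPPO signalling, photodynamic therapy, osteosarcoma growth in the tibia and spread to the lung, and the design names treated and untreated cells as the comparison. Photodynamic therapy uses a compound that forms reactive oxygen species under light. There were 3 libraries from cells given PBS and 3 from cells given TPBC-PEG for 24 h. The sample titles give the TPBC-PEG dose as 3 µM, while the treatment protocol gives 300 µM, so the dose of these samples is not settled. The labels do not say whether the sequenced cells had been exposed to light. The PBS libraries held 19412955, 18186250 and 16328710 counts, and the TPBC-PEG libraries 19171372, 20486584 and 15726323. Nothing in the labels says that the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

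The libraries of a group resembled each other more than those of the other group. Pearson's r of log2 CPM across genes ran from 0.992 to 0.993 within groups and from 0.985 to 0.988 between them. The first principal component held 47.1% of the variance and parted the groups. Counts of replicate libraries differed by more than sampling noise (chi-square per degree of freedom 2.19 to 4.04), so no library was a copy of another. Mitochondrially encoded mRNAs took 5.80% ± 0.466 of the counts with PBS and 4.81% ± 0.0957 with TPBC-PEG (mean ± SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The 10 most abundant genes took 7.11% ± 0.395 and 6.72% ± 0.113 (exact permutation p = 0.2, n = 3).

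The comparison asks which transcripts differ after TPBC-PEG, with genes of the Hippo pathway as a stated interest of the study. TPBC-PEG was followed by higher mRNA of endoplasmic reticulum chaperones and of the integrated stress response, and by lower mRNA of DNA replication and actin genes. HSPA5, which encodes the endoplasmic reticulum chaperone BiP, rose from 931 ± 34.2 to 3829 ± 531 CPM (mean ± SD, n = 3). DDIT3, which encodes the stress transcription factor CHOP, rose from 3.43 ± 0.213 to 21.7 ± 4.62 CPM. TYMS, which encodes thymidylate synthase, fell from 444.7 ± 3.74 to 301.6 ± 6.39 CPM. YAP1 and WWTR1, the coactivators that the Hippo kinases restrain, did not pass the test as set beforehand, while ANKRD1 and CCN2, which these coactivators are known to induce, fell.

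Of 15846 genes tested, 2574 were higher and 2682 lower in TPBC-PEG, 33.2% in all, at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Most of these changes were small: 84.3% were under 1.5-fold, and the median absolute log2 fold change of the called genes was 0.29. A change of at least 2-fold was seen for 249 genes that rose and 52 that fell. Tested against a 1.5-fold change instead of none, 131 genes were higher and 14 lower. The 3 values of one group did not overlap the 3 of the other for 43.4% of genes, where chance gives 10%. The balance of directions depended on scaling, since with library size alone 3213 genes were higher and 1971 lower.

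**Figure D1:**
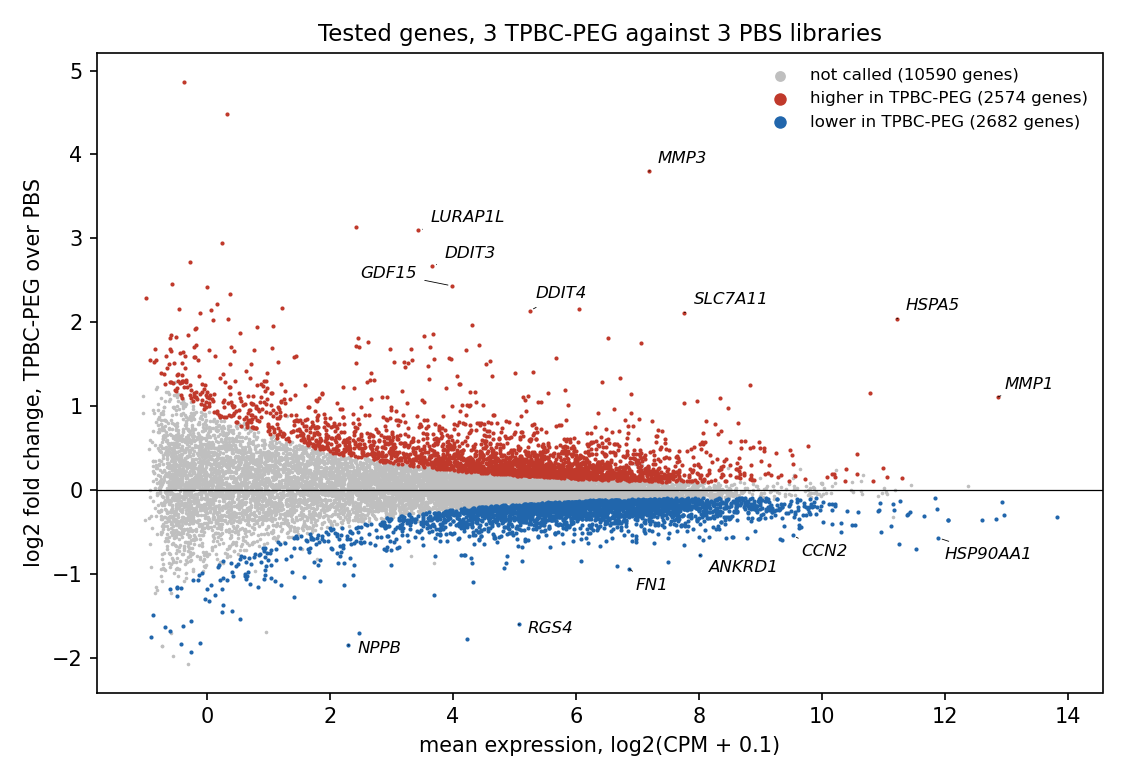
Each point is one of the 15846 tested genes. The horizontal axis is the log2 of the mean CPM over the 6 libraries plus a small constant, and the vertical axis is the log2 fold change of TPBC-PEG over PBS. Red points are the 2574 genes higher and blue points the 2682 genes lower in TPBC-PEG, and the changes above 2-fold lie mostly on the upper side, with MMP3 at 3.80.

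Among called genes with at least 5 CPM in a group and no overlap between groups, the largest rise was that of MMP3, a matrix metalloproteinase (stromelysin) on chromosome 11, 102835801 to 102843803 in GRCh38, from 19.5 ± 1.15 to 271.1 ± 45.2 CPM, a log2 fold change of 3.80 ± 0.18 (SE). LURAP1L rose by 3.10 ± 0.14, DDIT3 by 2.67 ± 0.14 and GDF15, a secreted stress-induced cytokine, by 2.43 ± 0.11. PTGS2, the inducible cyclooxygenase, rose by 2.16 ± 0.09, from 24.2 ± 2.37 to 108.2 ± 13 CPM. DDIT4, an inhibitor of mTORC1 signalling, rose by 2.14, SLC7A11, the cystine importer, by 2.12, and HSPA5 by 2.04. ERO1B, an oxidase that serves disulfide formation in the endoplasmic reticulum, rose by 1.96, KLHL24 by 1.86 and SMIM14 by 1.84. The smallest p-values among rises belonged to ALDH1L2, a mitochondrial folate enzyme, DDIT4, WARS1, the cytosolic tryptophanyl-tRNA synthetase, SQSTM1, the autophagy receptor p62, and SLC3A2, the partner chain of SLC7A11. ALDH1L2 rose by 1.81 ± 0.052 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.92e-31). RPLP0P2, a transcribed pseudogene of a ribosomal protein gene, also stood among the largest rises at 3.13, and its reads can be shared with its parent gene.

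Among the falls under the same conditions, the largest was that of NPPB, which encodes the B-type natriuretic peptide, from 7.48 ± 0.787 to 2.11 ± 0.561 CPM, a log2 fold change of -1.85 ± 0.18 (SE). IGFBP5, an insulin-like growth factor binding protein, changed by -1.71 ± 0.16 and RGS4, a regulator of G-protein signalling, by -1.60 ± 0.071. CPA4, a carboxypeptidase gene, fell from 17.9 ± 1.6 to 7.58 ± 1.19 CPM. The log2 fold change was -1.14 for MAP2K6, a kinase upstream of p38, -1.10 for KLF2, -1.02 for LYPD1, -0.94 for FN1, -0.93 for MEST, -0.90 for PLK2 and -0.89 for the unnamed gene ENSG00000279348 on chromosome 2. The smallest p-values among falls were those of RGS4, ANKRD1, PLK2, CALD1 and TGFBI. Exons of DDIT3, DDIT4 and LYPD1 overlap other annotated genes over 39.6%, 41.2% and 48.9% of their length. For MEST, SQSTM1 and WARS1 the overlap is 27.4%, 22.0% and 10.6%. The counts of these genes are less certain, since the strand setting of the counting is not given.

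The integrated stress response list, genes downstream of the transcription factors ATF4 and CHOP, moved together: all 22 measured members rose, with a median log2 fold change of 1.00. DDIT3 led, and NUPR1 rose by 2.33 from a low level of 0.397 ± 0.0943 CPM. Of 21 genes for endoplasmic reticulum chaperones and the unfolded protein response, 20 rose, with a median of 0.79. HERPUD1, which serves degradation of misfolded proteins at the endoplasmic reticulum, rose from 61.1 ± 2.08 to 205.2 ± 22.1 CPM. Adjusted over the list alone, the counts were also 22 and 20. Camera gave adjusted p = 3.07e-66 and 9.21e-62 for these lists (Benjamini-Hochberg over 41 lists), and 0.0498 for each with an estimated correlation.

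Other stress lists moved apart. Of 19 measured NRF2 target genes, 12 rose and 2 fell, both over all genes and adjusted over the list alone. SLC7A11 and HMOX1, the inducible haem oxygenase (1.01 ± 0.088), rose, while AKR1C3 and TKT fell, at -1.08 and -0.14. Among 20 ferroptosis regulators, 10 rose, SLC7A11 and PTGS2 the most, and 3 fell (4 adjusted over the list alone), with STEAP3 and ACSL4, the enzyme that loads polyunsaturated fatty acids, down, at -0.27 and -0.22. The heat shock list went down: 13 of 18 members fell and none rose, again 13 adjusted over the list alone, with a median of -0.31. HSP90AA1 and HSPH1, cytosolic chaperone genes, fell, at -0.57 and -0.42. Of 19 antioxidant enzymes 2 rose and 7 fell, the same numbers adjusted over the list alone, among them GLRX up at 0.61 and PRDX2 down at -0.42. Of 6 metallothioneins 1 fell, MT1E at -0.14, and 0 did adjusted over the list alone. MT1E was not called without PBS replicate 1, TPBC-PEG replicate 1 or TPBC-PEG replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.166, 0.19 and 0.0785). In the autophagy and lysosome list 8 genes rose and 5 fell of 26 (9 and 5 adjusted over the list alone), with SQSTM1 named above, and WIPI1 and GABARAPL1 up by 1.73 and 1.16. Camera called the NRF2, ferroptosis and autophagy lists higher (adjusted p = 3.3e-11, 9.29e-14 and 0.0012) and the heat shock list lower (2.45e-10), but not the antioxidant enzymes (0.214) or metallothioneins (0.495). With an estimated correlation the adjusted p was 0.0498 for NRF2 and ferroptosis, 0.0749 for autophagy and adjusted p = 0.0749 for heat shock.

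**Figure D2:**
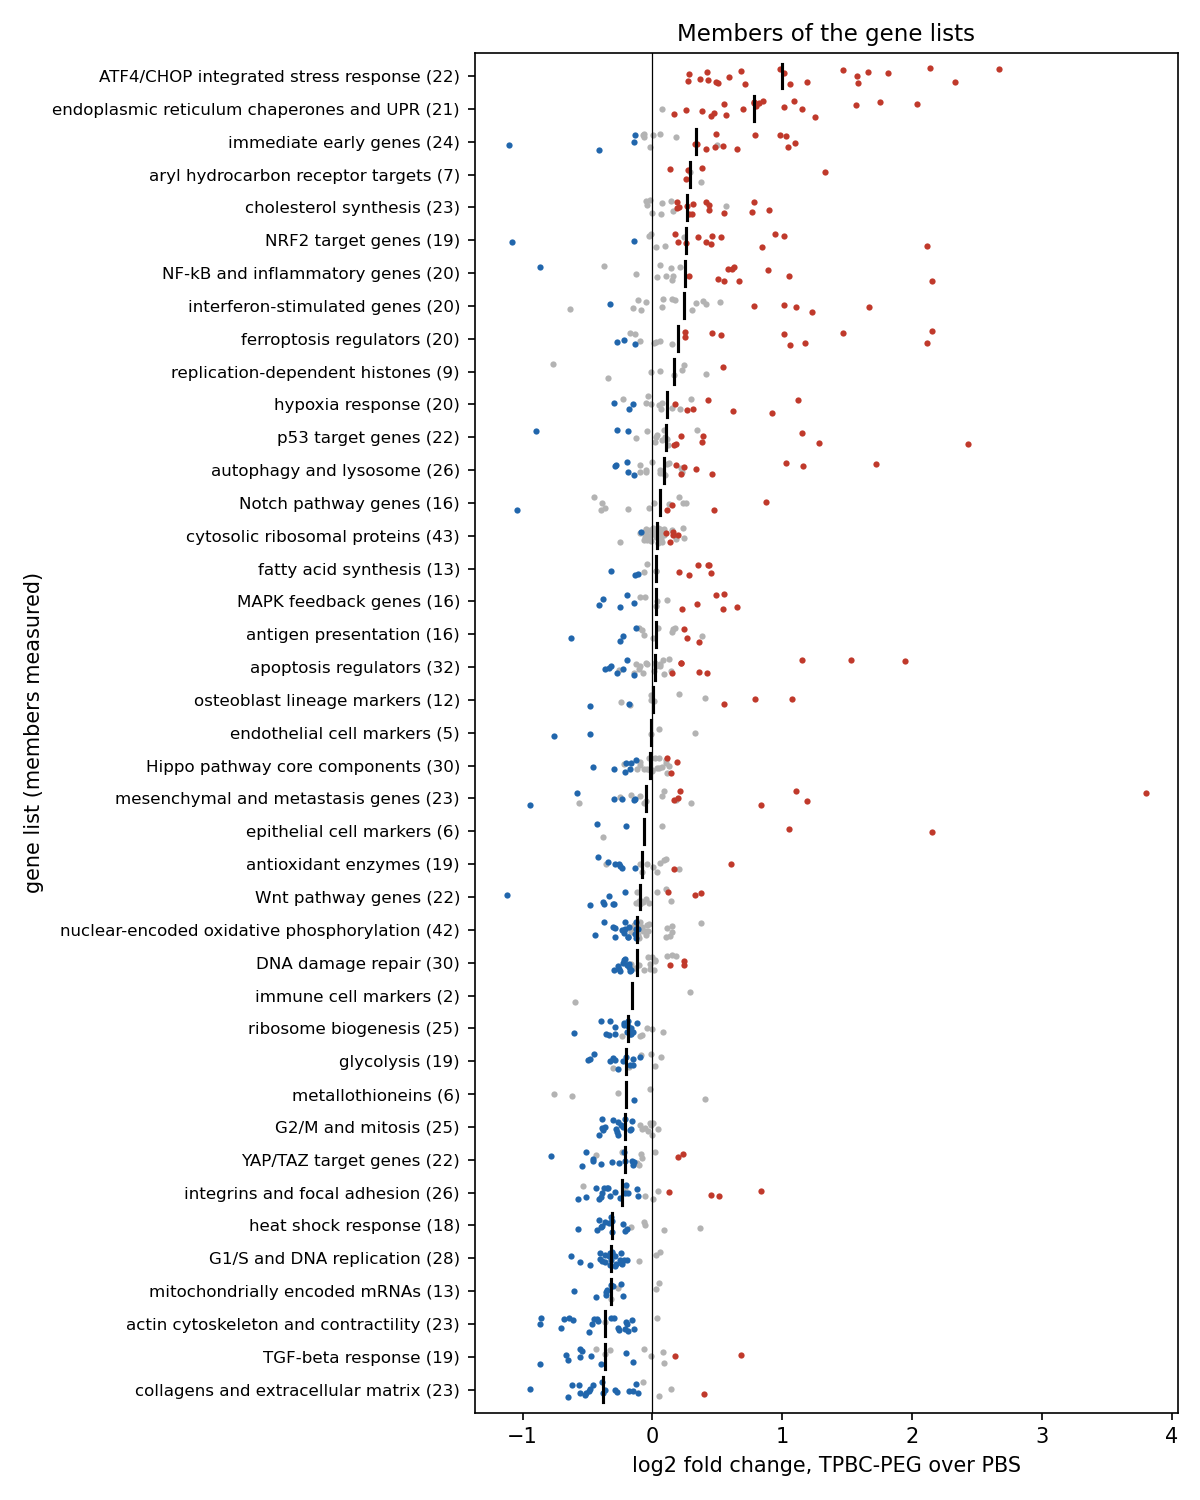
Each row is one of the 41 gene lists, with the number of members measured in brackets, sorted by the median. Points are the log2 fold changes of single members, TPBC-PEG over PBS, in red or blue where the gene passed the test and in grey where it did not, and black bars are list medians, which run from -0.38 for collagens and extracellular matrix to 1.00 for the integrated stress response.

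Of 30 Hippo core components 20 did not pass the test, and of 22 genes known as YAP and TAZ targets 13 fell and 2 rose. YAP1 (chromosome 11, 102110461 to 102233423) stood at 300.8 ± 12.3 CPM with PBS and 307.6 ± 3.51 with TPBC-PEG, a log2 difference of 0.032 ± 0.037 (SE). WWTR1, which encodes TAZ, stood at 208 ± 7.67 and 215.4 ± 3.87 CPM, and TEAD1, the DNA-binding partner of both, at 280.3 ± 9.57 and 279.4 ± 4.17. None of these passed the test, and the sign of each small difference turned under another setting. The kinase genes LATS1, LATS2 and STK4 did not pass either, at 0.075, -0.12 and 0.051. With the trend of fold change on expression level removed, a setting chosen after the results were seen, YAP1, WWTR1 and STK4 passed as higher, each at 0.11 (adjusted p = 0.0165, 0.0179 and 0.0151, edgeR quasi-likelihood, Benjamini-Hochberg). STK4 also passed with library size alone (0.094, adjusted p = 0.0476, edgeR quasi-likelihood, Benjamini-Hochberg). STK3 (MST2) and the kinase adaptor MOB1A fell, at -0.20 and -0.13 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0157 and 0.0126). The STK3 call was lost without PBS replicate 1 (adjusted p = 0.057, edgeR quasi-likelihood, Benjamini-Hochberg), without TPBC-PEG replicate 1 (0.0694) and with library size alone (0.0669). The MOB1A call was lost without PBS replicate 1 (adjusted p = 0.0649, edgeR quasi-likelihood, Benjamini-Hochberg), without TPBC-PEG replicate 3 (0.0685), with library size alone (0.113) and with the expression-level trend removed (0.213). Of 30 Hippo core components 3 rose and 7 fell, the same numbers adjusted over the list alone, with AMOTL2, an angiomotin family gene that is also a YAP1 target, at -0.46 and NF2, the merlin gene, at -0.29. Camera did not call this list (adjusted p = 0.344).

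ANKRD1 fell from 325.5 ± 5.94 to 189.7 ± 12.2 CPM, a log2 fold change of -0.78 ± 0.040 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.82e-21). CCN2 (chromosome 6, 131948176 to 131951373) fell from 871.5 ± 20.6 to 599.3 ± 44.4 CPM, and AMOTL2 from 158.9 ± 12.2 to 115.7 ± 2.12. CCN1, another standard target, was at 561.5 ± 17.7 and 527.6 ± 26.5 CPM and missed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0598). CCN1 passed without PBS replicate 1 (adjusted p = 0.0209, edgeR quasi-likelihood, Benjamini-Hochberg) and without TPBC-PEG replicate 3 (0.00933). It also passed with DESeq2 size factors (adjusted p = 0.0442, edgeR quasi-likelihood, Benjamini-Hochberg), with limma-voom (0.0382) and with the GC trend removed (0.0158), and was at -0.00062 with the expression-level trend removed (0.993). Of 22 YAP and TAZ target genes 13 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.21, and the rises were IGFBP3 at 0.23 and GADD45A at 0.20. Camera called the list lower (adjusted p = 4.04e-07), a call lost with an estimated correlation (adjusted p = 0.0918 with an estimated correlation).

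**Figure D3:**
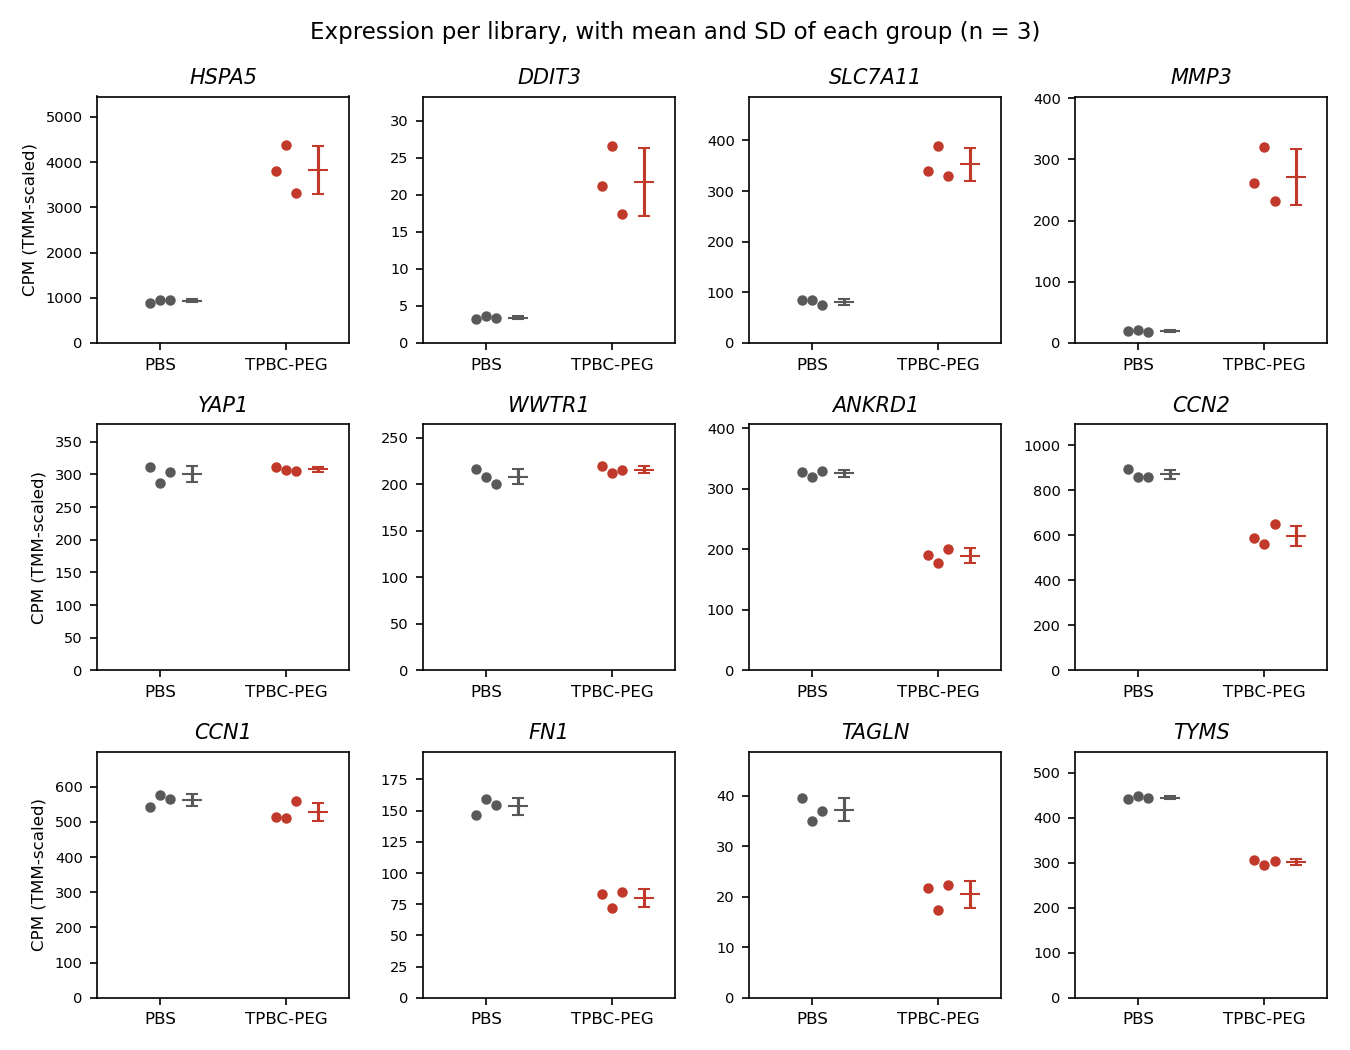
Expression of 12 genes in each library, in CPM scaled by TMM on axes that start at 0. Points are single libraries, grey for PBS and red for TPBC-PEG, with the mean and SD of each group (n = 3) beside them. YAP1 and WWTR1 overlap between groups, while HSPA5, DDIT3, SLC7A11 and MMP3 lie higher and ANKRD1, CCN2, FN1, TAGLN and TYMS lower in TPBC-PEG, as with HSPA5 at 931 against 3829 CPM.

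Most genes of the actin, matrix and adhesion lists fell. Of 23 actin cytoskeleton genes 21 fell and none rose, the same adjusted over the list alone, with a median of -0.36. TAGLN, which encodes the actin-binding protein transgelin, was at -0.87 ± 0.08 (SE) and CALD1, caldesmon, at -0.86 ± 0.044. Of 23 collagens and matrix genes 19 fell and 1 rose, also adjusted over the list alone, with FN1, fibronectin, down from 153.4 ± 6.74 to 79.98 ± 6.99 CPM, COL8A1 at -0.65 and TNC, tenascin C, up by 0.40. Of 26 integrin and focal adhesion genes 17 fell and 4 rose, also adjusted over the list alone. VCL, vinculin, and ITGA4 fell, at -0.57 and -0.51, and ITGA11 rose by 0.84. In the TGF-beta response list 10 of 19 fell and 2 rose (11 and 3 adjusted over the list alone), with ID1 at -0.66 and BHLHE40 at 0.69. Camera called these lists lower, with adjusted p = 4.98e-24 for actin, 2.55e-13 for matrix, 4.04e-07 for integrins and 1.04e-06 for TGF-beta. With an estimated correlation the adjusted p was 0.0498 for actin, 0.0918 for matrix, 0.157 for integrins and 0.0741 for TGF-beta. The lists share genes: TAGLN stands in the actin and TGF-beta lists, CCN2 in the TGF-beta and YAP lists, and FN1 in the matrix and mesenchymal lists.

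Mesenchymal and metastasis genes went both ways, with 7 of 23 up and 6 down (8 and 6 adjusted over the list alone). MMP1, the interstitial collagenase, rose by 1.11 ± 0.043 from 4724 ± 125 CPM with PBS, and PLAU, urokinase, fell by 0.58 ± 0.05. The median of this list was -0.051 and its mean 0.20, and camera, which pointed up, did not call it (adjusted p = 0.214). MMP3, at 3.80, is a member, and the mean of the other 22 was 0.038. Without TPBC-PEG replicate 2 or 3 camera did call the mesenchymal list (adjusted p = 0.000544 and 0.0392). Of 12 osteoblast lineage markers 3 rose, led by BMP2 at 1.07 and SPP1, osteopontin, at 0.79, and 2 fell, COL1A1 at -0.48 and SPARC at -0.18, the same numbers adjusted over the list alone (camera adjusted p = 0.299).

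Most genes of the DNA replication and division lists fell, by modest amounts. Of 28 G1/S and DNA replication genes 25 fell and none rose, also adjusted over the list alone, with a median of -0.32. TYMS was at -0.56 ± 0.036 (SE), although it shares 46.6% of its exon length with another annotated gene. Of 25 G2/M genes 16 fell and none rose, also adjusted over the list alone, with KIF11, a spindle kinesin, at -0.41 and the kinase gene AURKB at -0.39. In the DNA damage repair list 12 of 30 fell and 3 rose (15 and 3 adjusted over the list alone), with PARP1 at -0.29 and XRCC5 at -0.27 against ATM and BRCA2, both at 0.24. Of 25 ribosome biogenesis genes 19 fell (20 adjusted over the list alone) and none rose, led by BOP1 at -0.61. Camera gave adjusted p = 1.4e-17, 6.02e-09, 0.0147 and 2.92e-08 for G1/S, G2/M, repair and ribosome biogenesis. With an estimated correlation the adjusted p was 0.0498, 0.0589, 0.0962 and 0.0741 in that order. Of 43 cytosolic ribosomal protein genes 5 rose, RPL3 the most at 0.19, and 1 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.524). Of 9 replication-dependent histone genes 1 rose, H2BC21 at 0.55, also adjusted over the list alone (camera adjusted p = 0.625).

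Among metabolic lists, part of the mitochondrial and glycolytic genes fell and part of the cholesterol synthesis genes rose, and no list call among these held with an estimated correlation. Of 13 mitochondrially encoded mRNAs 9 fell (10 adjusted over the list alone), with MT-ND5, a complex I subunit, down from 2560 ± 242 to 1897 ± 41.2 CPM. The lower share of mitochondrial mRNA in the TPBC-PEG libraries given above comes from the counts of the same genes and is not separate evidence. Of 42 nuclear genes of oxidative phosphorylation 17 fell (19 adjusted over the list alone), with ATP5MC1 at -0.44, and of 19 glycolysis genes 13 fell (14 adjusted over the list alone), with LDHA at -0.50 and PGAM1 at -0.48. None of these 3 lists held a gene that rose. Camera called them lower (adjusted p = 5.78e-06, 0.000152 and 6.54e-07), and with an estimated correlation the adjusted p was 0.264, 0.215 and 0.125. Of 23 cholesterol synthesis genes 14 rose (15 adjusted over the list alone) and none fell, led by INSIG1 at 0.90 and STARD4 at 0.78. In the fatty acid list 6 of 13 rose, FADS1 and FADS2 at 0.45 and 0.43, and 3 fell, SREBF1 at -0.32 among them, the same adjusted over the list alone. In the hypoxia list 7 of 20 rose and 3 fell (9 and 3 adjusted over the list alone), with NDRG1 up by 1.12, VEGFA by 0.92 and PFKFB3 down, at -0.29. Camera called cholesterol, fatty acid and hypoxia lists higher (adjusted p = 1.47e-08, 0.045 and 0.00163), and with an estimated correlation the adjusted p was 0.0741, 0.215 and 0.26. The fatty acid call was also lost without PBS replicate 1 or 3 (camera adjusted p = 0.081 and 0.0634) and without TPBC-PEG replicate 2 or 3 (0.0579 and 0.0635).

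Several inflammatory genes rose. Of 20 measured NF-kB and inflammatory genes 10 rose, PTGS2 and IL1A (1.05) the most, and 1 fell, the chemokine CXCL1 at -0.87, the same adjusted over the list alone. Of 24 immediate early genes 12 rose, FOSB at 1.10 and JUND at 1.04 leading, and 4 fell, KLF2 at -1.10 and DUSP6 at -0.41 among them, also adjusted over the list alone. Of 7 measured aryl hydrocarbon receptor targets 5 rose, also adjusted over the list alone, with CYP1B1, a xenobiotic-metabolising enzyme, at 0.38. Camera called these 3 lists higher (adjusted p = 2.36e-05, 0.00406 and 0.00328), and with an estimated correlation the adjusted p was 0.0498, 0.08 and 0.17. Of 20 interferon-stimulated genes 5 rose, OASL at 1.67 and IFIT2 at 1.23 from low levels, and 1 fell, OAS3 at -0.33, the same adjusted over the list alone (camera adjusted p = 0.112). Of 16 antigen presentation genes 3 rose and 4 fell, with ERAP1 at 0.36 and TAP2 at -0.25, the same adjusted over the list alone (camera adjusted p = 0.969).

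Of 22 p53 target genes 8 rose, GDF15 and TP53INP1 (1.28) the most, and 3 fell, PLK2 and BAX (-0.28) among them, the same adjusted over the list alone. Camera called the p53 list higher (adjusted p = 0.0463), a call lost without PBS replicate 1 (0.0848), without TPBC-PEG replicate 3 (0.0635) and with an estimated correlation (adjusted p = 0.157 with an estimated correlation). Apoptosis regulators went both ways: 8 of 32 rose and 7 fell (8 and 8 adjusted over the list alone). HRK and BMF, which encode BH3-only proteins that promote apoptosis, rose by 1.95 and 1.53, and BCL2L1, whose long form opposes it, fell by 0.37 (camera adjusted p = 0.637). HRK rose from a low level of 0.685 ± 0.117 CPM, and exons of BCL2L1 overlap other annotated genes over 43% of their length. In the Wnt list 3 of 22 rose and 8 fell (4 and 9 adjusted over the list alone), with MYC at 0.32, LGR5 at -1.12 from 2.08 ± 0.252 CPM and TCF7 at -0.48. Camera called the Wnt list lower (adjusted p = 0.0309), lost without TPBC-PEG replicate 2 (0.0579) and with an estimated correlation (adjusted p = 0.26 with an estimated correlation). Of 16 Notch pathway genes 4 rose, HEY1 at 0.87 and JAG1 at 0.47 leading, and 1 fell, NOTCH3 at -1.04, the same adjusted over the list alone. The Notch median was 0.061 and its mean -0.026 (0.042 without NOTCH3), with camera pointing up (adjusted p = 0.627). Of 16 MAPK feedback genes 6 rose and 5 fell (7 and 5 adjusted over the list alone), with DUSP5 at 0.65 and CCND1 at -0.38 (camera adjusted p = 0.105).

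Markers of other cell types gave no common direction. Of 6 measured epithelial markers 2 rose, CLDN3 and ESRP1, both at under 2 CPM in each group, and 2 fell, KRT18 at -0.42 and KRT8 at -0.21, the same adjusted over the list alone. The epithelial median was -0.066 and the mean 0.38, with camera pointing down (adjusted p = 0.495). Without ESRP1, at 2.15, the epithelial mean was 0.023. Of 5 endothelial markers 2 fell, FLT1 at -0.48 and ESAM, and 0 rose (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.514). ESAM lost its call without PBS replicate 1 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.125 and 0.138) and without TPBC-PEG replicate 2 or 3 (0.239 and 0.0696), and CLDN3 without PBS replicate 3 (0.0949) or TPBC-PEG replicate 2 (0.0547). Of 16 immune cell markers 2 were measured, ITGAX and CD14, and neither passed, over all genes or adjusted over the list alone. ITGAX passed as higher without PBS replicate 2 (adjusted p = 0.0196, edgeR quasi-likelihood, Benjamini-Hochberg), with library size alone (0.0427) and with the GC trend removed (0.0406). The immune median and mean were -0.16, while camera pointed up (adjusted p = 0.969).

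In all, camera with a preset correlation of 0.01 called 12 lists higher and 14 lower, and with an estimated correlation 5 higher and 2 lower. The latter rests on 4 residual degrees of freedom per gene, so a call lost with it does not show that the list did not move. The 7 lists that held were NRF2 targets, endoplasmic reticulum chaperones, integrated stress response, ferroptosis and NF-kB, higher, and G1/S and actin, lower, each at an adjusted p of 0.0498. Benjamini-Hochberg adjustment can give lists of unlike strength the same value, so this shared value does not rank these lists. The value lies just under the threshold of 0.05, so these calls are narrow. The estimated correlation was not tried with single libraries left out. Some of these lists share members and are not separate evidence: of the 10 ferroptosis genes that rose 7 stand in other lists, SLC7A11, HMOX1, FTH1 and FTL among NRF2 targets, SLC3A2 and CHAC1 in the integrated stress response and PTGS2 in NF-kB. The preset test also called 6 to 15 lists in splits of the libraries that mixed the groups. In these splits edgeR's quasi-likelihood test called 0 genes (176 to 374 at an unadjusted p under 0.05) and DESeq2 at most 1. The groups are unevenly divided in every mixed split, so part of the group difference remains in it. The mixed splits therefore do not show how often camera calls lists falsely. Most preset calls were lost with an estimated correlation, so a preset call alone is weak evidence here. Fry, which tests whether a list moves one way on balance without comparing it with other genes, called 17 lists higher and 18 lower. Where no gene of a list was called in a direction, edgeR's quasi-likelihood test at an unadjusted p under 0.05 gave 0 genes in that direction too, apart from 1 higher endothelial marker, 1 higher immune cell marker and 1 lower histone gene, and limma-voom and DESeq2 called 0.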

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

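The trend offsets and the run on protein-coding genes were chosen after the results were seen; the other alternatives were planned. Counts of called genes stayed within 1.5 times their value under other scalings, filters, limma-voom and non-robust estimation, and 98.4% of called genes stayed called with DESeq2 size factors and 75% with the DESeq2 test. With DESeq2, 1751 genes were higher and 2211 lower, of which 159 and 31 by at least 2-fold. The test against a 1.5-fold change gave 131 and 14, of which 106 and 6 by at least 2-fold, since it asks for a larger change. Protein-coding genes alone gave 164 and 25 by at least 2-fold, with 12931 genes tested. With an estimated correlation 5 lists were higher and 2 lower. Of the 149 named genes, 94 lost their call against a 1.5-fold change, 10 with the DESeq2 test, 9 with library size alone and 4 to 11 without single libraries.

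Leaving out each library in turn gave 1987 to 2347 genes higher and 2141 to 2515 lower, 217 to 267 and 50 to 64 by at least 2-fold, and 10 to 12 lists higher and 13 to 14 lower. No pairing by replicate number was seen: between groups, deviations of libraries with the same number correlated at -0.0154 to 0.0646. Those with different numbers correlated at -0.0548 to 0.0509. These values cannot show whether the samples were prepared in pairs. With the replicate number as a block 2531 genes were higher and 2644 lower (246 and 51 by at least 2-fold), and 13 lists higher and 14 lower. The block lost 2 of the 149 named genes, STRN3 (adjusted p = 0.0507) and MT1E (0.052), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and added the mesenchymal and metastasis genes (camera adjusted p = 0.00097).

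The differences that reversed had not passed the test and did not pass after reversing; the cause was not tested. TEAD1 was 0.039 with library size alone, 0.00036 with upper quartile scaling, -0.025 to 0.016 without single libraries (0.016 without PBS replicate 1, 0.0069 without TPBC-PEG replicate 1), 0.069 with the expression trend removed and 0.0035 among protein-coding genes. YAP1 was -0.0021 to 0.050 without single libraries, the lowest without PBS replicate 2, and -0.0043 with the GC trend removed, and WWTR1 -0.00016 with the latter. With the expression trend removed YAP1 was 0.11 and WWTR1 0.11, and both passed as higher (adjusted p = 0.0165 and 0.0179, edgeR quasi-likelihood, Benjamini-Hochberg). Camera's direction turned for 2 lists, immune cell markers (medians -0.11 with library size alone, -0.45 to 0.099 without single libraries, -0.25 with the expression trend removed) and antigen presentation (0.019 without a filter, -0.054 to 0.15 without single libraries, -0.034 with the expression trend removed). Further list calls changed, by camera adjusted p. With the expression trend removed the DNA repair call was lost (0.0908), and the ribosomal protein (3.38e-06), MAPK feedback (0.00707) and mesenchymal (0.0347) lists were called higher. Library size alone added MAPK feedback (0.041) and no filter the interferon list (0.0465). The stricter filter lost p53 and fatty acid (both 0.0537), fatty acid was lost with the exon length trend removed (0.0728), and Wnt was lost with the GC trend removed (0.051) and among protein-coding genes (0.0579). The p53, Wnt and fatty acid medians, 0.103, -0.0961 and 0.0304, lay inside the central 95% of expression-matched random lists. The simulated test found 80% of 1.5-fold changes, with 200 of 15846 genes changed. In the real data 5256 genes were called, which eases the adjusted threshold, so that share does not carry over. Small changes of single genes can still be missed.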

Other observations

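The gene groups of this part, the expression-matched tests and the trend offsets were chosen after the results were seen. The predictions for the splits of the libraries and for overlapping genes were written before those tests were run. The non-coding pattern that the overlap test addresses was itself seen in these data. The named genes of these groups were chosen after their values were seen, and a group picked from its leading genes is not independent evidence of its direction. The camera p-values of the groups chosen here were adjusted over those groups alone. They cannot be ranked against those of the lists fixed beforehand. Amino acid transporter genes rose: 10 of 15 were higher and 0 lower, with a median log2 fold change of 0.37 (camera adjusted p = 0.031 with an estimated correlation). SLC6A9, a glycine transporter, rose by 1.68 ± 0.13 (SE, n = 3), from 4.68 ± 0.476 to 15.1 ± 2.02 CPM, and SLC1A5, the neutral amino acid transporter, by 0.46 ± 0.038. SLC7A11, SLC3A2 and SLC7A5 were among those that rose and are also members of lists fixed beforehand, so the group is not separate evidence. Genes for vesicle coats leaving the endoplasmic reticulum and for protein entry into it rose in 17 of 24 cases with 0 lower, led by SEC24D at 0.91 and TRAM1 at 0.70 (camera adjusted p = 0.031 with an estimated correlation).

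Tubulin genes fell: 8 of 11 measured alpha- and beta-tubulins were lower, TUBB at -0.50 from 2343 ± 72.2 CPM and TUBB4B at -0.57, while TUBA1A rose by 0.39 (camera adjusted p = 0.0431 with an estimated correlation). Tubulin genes are near copies of each other, and how the authors' counting split their reads is not given in the sources used here. The 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, all fell, by 0.12 to 0.28 (camera adjusted p = 0.0972 with an estimated correlation), and 7 of 12 SR splicing factor genes fell, SRSF6 the most at -0.47 (0.0771). The CCT and SR medians, -0.177 and -0.16, lay inside the central 95% of expression-matched random lists (-0.227 to 0.0619 and -0.19 to 0.0713), so these groups were not shown to stand apart from other genes at their expression. NPPB, ANKRD1 and EDN1, the measured members of a list of natriuretic peptide and stretch-response genes, all fell, EDN1 by 0.79 ± 0.075.

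Long non-coding genes, here those annotated as antisense, lincRNA, processed transcript, sense intronic, sense overlapping or bidirectional promoter, rose more often than they fell. Of 1815 tested 249 rose and 55 fell, so 81.9% of those called rose (95% exact interval 77.1 to 86.1), against 46.4% of protein-coding genes. These shares are not like for like, since genes with few counts are called mainly for large changes. Large changes of protein-coding genes were mostly rises too: tested alone, 164 rose and 25 fell by at least 2-fold. The median at matched expression, given below, is the closer comparison. Other gene types are not in these counts, and they went both ways. Transcribed pseudogenes mostly rose too: 33 unprocessed ones rose and 7 fell, and 7 processed ones rose and 2 fell. The rise was thus not particular to long non-coding genes. Processed pseudogenes were balanced, with 19 up and 21 down. Of 28 snoRNA genes 0 rose and 6 fell, and of 6 mitochondrial tRNA genes 0 rose and 4 fell by edgeR's quasi-likelihood test. For these 2 types there were 0 rises also at an unadjusted p under 0.05 and with limma-voom or DESeq2. The protein-coding share of the counts was 96.75% ± 0.0872 with PBS and 96.57% ± 0.0346 with TPBC-PEG (exact permutation p = 0.1, n = 3). Reads of overlapping genes, a GC trend and an expression-level trend were each argued against as the whole cause: without exon overlap the share was 79.5%, with the GC trend removed 80.6%, and the median of 0.154 lay above the central 95% of 10000 expression-matched protein-coding sets (0.0484 to 0.0717). Removing the expression-level trend lowered the share to 72.6%, so that trend may be part of it. Reads from introns or unspliced RNA stay open, since gene counts cannot show them, and a response to TPBC-PEG is a candidate explanation that the design cannot separate from other differences between the groups.

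Most genes of the YAP and TAZ target list and of the actin list fell, while YAP1 and WWTR1 mRNA did not pass the test as set beforehand and passed as higher with the expression-level trend removed (adjusted p = 0.0165 and 0.0179, edgeR quasi-likelihood, Benjamini-Hochberg). With that trend removed the list medians were -0.125 and -0.347. The higher of the medians of these lists, -0.213, lay below the central 95% of 10000 expression-matched random lists (lower bound -0.139), and it was -0.197 with the GC trend removed and -0.218 with the exon length trend removed. This argues against each of these trends as the whole cause, while an expression-level trend may be part of the YAP and TAZ value. The fall is in line with lower YAP1 and TAZ activity or lower SRF activity, as a hypothesis; protein location and phosphorylation, which would bear on it, were not analysed here. Since the YAP and TAZ list lost its call with an estimated correlation (adjusted p = 0.0918), the hypothesis rests on single genes such as ANKRD1 and CCN2 and on the actin list. Other targets did not go with it: CCN1 did not pass the test as set beforehand, and IGFBP3 and GADD45A rose. The actin list does not tell lower YAP1 and TAZ activity from lower SRF activity.

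WARS1, SARS1 and other cytosolic aminoacyl-tRNA synthetase genes rose, but the group was mixed: of 20, 10 rose and 7 fell, VARS1 at -0.42 among them. The list was not called with an estimated correlation (camera adjusted p = 0.0809). Its median of 0.12 lay above the central 95% of expression-matched random lists (upper bound 0.0159), but a median over members that go both ways decides nothing, so an expression-level trend stays open. Of 17 mitochondrial synthetase genes 1 rose and 7 fell, with a median of -0.0861. These values argue against a rise shared by the mitochondrial group as a set. The cytosolic and mitochondrial medians differed by 0.206 (two-sided permutation test over genes with 100000 resamples, p = 0.119), with members going both ways in each. That test therefore did not show a difference between the groups. A response through ATF4, which is known to induce WARS1 and SARS1 among others, is a candidate explanation and was not tested.

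Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes as the groups did, which was the grouping itself, with 5256 genes against 0 as the highest of the others by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 that test gave 6579 genes for the grouping and 176 to 374 for the others. With limma-voom the grouping gave 5209 genes and the others 0, and with DESeq2 it gave 3962 and the others at most 1. For changes of at least 2-fold the values were 301 and 0, and for gene lists 26 and 15. So few splits cannot give a share under 0.05. The other splits also keep part of the group difference, and the rest of it widens the spread within their sides. They are therefore no picture of libraries without a difference.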
